A study of Mus musculus with 6 samples.

How the data were processed

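RNA sequencing was carried out on whole epidermis of 3 C57BL/6 mice aged 6 to 8 weeks. Per the labels' protocols, 8 wounds were made in the back with a 3 mm punch biopsy and wounded tissue was collected 2 h later. No collection time was taken from the labels for the non-wounded tissue. The epidermis was separated from the dermis in trypsin, RNA was extracted with Trizol and a column kit, and libraries were made by poly-dT capture. Each mouse gave 1 library of non-wounded and 1 of wounded tissue, so that there were 3 libraries per group and 6 in all. Libraries were grouped by the labels, and the 3 replicates of a group are separate mice.

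The authors deposited estimated counts per gene symbol, called raw counts in the file header, and a second table of the same libraries in TPM (transcripts scaled to a fixed total). Per the deposited methods sheet and the submitters' processing notes, both come from Salmon with the mouse genome build mm10, and expression was compared with edgeR. That sheet lists the wounded against the non-wounded sample of each mouse as the comparisons. Tool versions, the annotation release and the strand setting are not given in the sources used here. Between 30.5% and 32.2% of the deposited estimated counts per library are not whole numbers. The tables hold 47455 gene symbols, of which 18905 have a count of 0 in all 6 libraries. Estimated counts divide reads that fit several transcripts, so values of near-identical genes are uncertain, and without a stated strand setting so are those of overlapping antisense genes.

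The estimated counts were rounded to whole numbers. Their totals were 23509424, 23537813 and 21802704 for the non-wounded libraries of mice 1, 2 and 3, and 23798928, 26815028 and 20746378 for the wounded ones. A count of 0 was taken to allow up to 3 counts per library, which corresponds to 0.143 CPM on average in the wounded libraries. Floors and counting intervals cover counting error only, since no molecular identifiers are named. Replicates differed by more than counting noise, with a chi-square per gene of 13.7 to 37.1 between libraries of a group over genes with at least 20 counts, so each library was counted separately.

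Genes were filtered with filterByExpr (16079 kept), scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, wounded against non-wounded, without a term for the mouse. CPM are counts divided by the total over the genes kept times the TMM factor. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The SE is the absolute log2 fold change divided by the square root of F. The test was tried on simulated counts for the 16079 genes of this comparison. It recovered 34%, 58%, 84% and 98% of 50 genes each changed 1.5-, 2-, 4- and 8-fold, and called 10 unchanged genes. The simulated changes went up and down in equal numbers, with no shift in library composition and no mouse effect. The simulation therefore does not give the error rate for data in which 48.4% of genes were called. An exact test of 3 against 3 libraries cannot give a two-sided p under 0.1, so single genes were tested only in models fitted across all genes. The TMM factors were 1.12 in each of the non-wounded and between 0.887 and 0.898 in the wounded libraries. Relative to TMM, library totals alone moved log2 fold changes by -0.32, upper-quartile factors by -0.15 and log2(TPM + 1) by -0.29 (median over genes), and log2 fold changes are reported relative to TMM.

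A set of 32 gene lists with 470 genes, covering pathways and cell types of skin and wounds, was fixed before the data were examined. All 470 were found, 5 of them under an older symbol (Il1f6, Il1f8, Il1f9, Il1f5 and Amica1). The 29 lists with at least 5 tested members (3 for red blood cells) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 29. The test was repeated with an estimated correlation and with fry. Counts of members adjusted over the list alone equalled those over all genes tested for 24 lists, and both are given for the other 8.

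The rule for named genes was also fixed before the data were examined. It takes Hspa8 and Icam1, then the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM and the same direction in all 3 mice, leaving out predicted genes, pseudogenes and receptor segments. It adds the 3 members with the smallest p of each list past the camera threshold and 1 of every other list. Some of the genes it takes are not reported here. Other list members and family members named in the text are examples chosen after their values were seen. Coordinates are 1-based and come from the GENCODE annotation of GRCm38 (mm10) supplied with the data, to which 46292 symbols were matched, and the authors' own release may differ.

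The labels place the 2 libraries of a number in 1 mouse, so the libraries are paired by animal, and this was checked. After removal of group means, the correlation across genes between the libraries of a mouse was 0.152 for mouse 1, 0.0409 for mouse 2 and 0.167 for mouse 3. Between a wounded and a non-wounded library of different mice it was lower, from -0.145 to 0.00587. Genes are not independent replicates. The fit without the mouse was kept as fixed beforehand, although the deposited sheet lists comparisons within mice. With the mouse as a block, 4212 genes were higher and 4351 lower, of which 3833 and 3891 were also called without it.

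The alternatives tried were RLE and upper-quartile factors, no filter and a filter of CPM of at least 1 in at least 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1) of the deposited TPM, the mouse as a block, a change of at least 2-fold, and leaving out each of the 6 libraries. Scaling by library totals alone was added after seeing the data. Tables and figures were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.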

Results

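The transcriptome of mouse epidermis was measured in 3 C57BL/6 mice, each of which gave 1 library from skin collected 2 h after punch wounding and 1 from non-wounded skin. The 6 libraries held between 20746378 and 26815028 counts. The comparison asks which transcripts change in epidermis soon after damage. The series title singles out Hspa8 and ICAM-1 in the activation of gd T cells, which in mouse epidermis are the dendritic epidermal T cells that sit among the keratinocytes. Expression is given as the mean ± SD of counts scaled by library size times the TMM factor (CPM) over 3 libraries per group. Log2 fold changes are wounded over non-wounded, with standard errors (SE), and adjusted p-values are from edgeR's quasi-likelihood test unless camera is named.

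Hspa8 and Icam1 both rose in wounded epidermis, in 3 of 3 mice. Hspa8, which encodes the constitutive cytosolic chaperone Hsc70, went from 680 ± 42.5 to 2154 ± 91.8 CPM, a 3.17-fold rise (log2 1.66, SE 0.10, adjusted p = 1.50e-06 by edgeR). Icam1, which encodes an adhesion receptor bound by leukocyte integrins, went from 33.1 ± 3.69 to 124 ± 0.889 CPM, a 3.74-fold rise (log2 1.90, SE 0.10, adjusted p = 1.16e-06 by edgeR). Both are protein-coding genes on the plus strand of chromosome 9 of GRCm38 (mm10). Hspa8 (ENSMUSG00000015656.17) spans 40800984 to 40810087 and Icam1 (ENSMUSG00000037405.8) spans 21015985 to 21028817. Over the alternatives and left-out libraries, the log2 fold change of Hspa8 lay between 1.34 and 1.70 and that of Icam1 between 1.51 and 1.98.

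**Figure D1:**
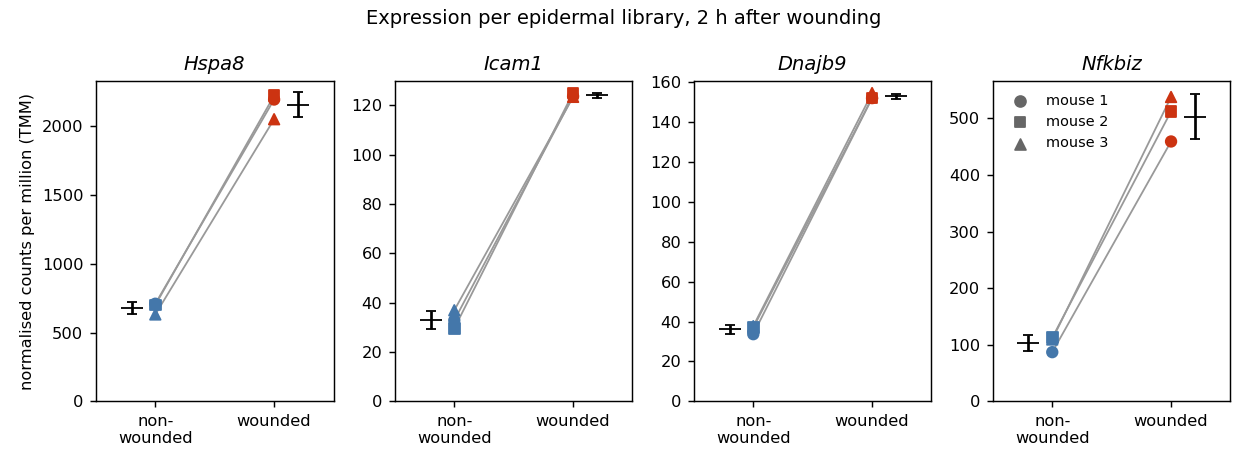
Normalised expression (TMM-scaled CPM, linear axis from 0) of Hspa8, Icam1, Dnajb9 and Nfkbiz in each library, with lines joining the libraries of 1 mouse and black bars for the mean ± SD of 3 libraries. In each panel all 3 wounded libraries lie above all 3 non-wounded ones.

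Across the transcriptome, 3859 genes were higher and 3917 lower in wounded epidermis, 48.4% of the 16079 tested, and 1414 and 1567 of these changed at least 2-fold. The direction was shared by all 3 mice for 3843 of the higher and 3897 of the lower genes. Higher genes made up 49.6% of calls under TMM scaling, 37.1% with upper-quartile factors (2979 higher, 5053 lower) and 24.6% with library totals alone (2168 higher, 6655 lower). With the deposited TPM, on log2(TPM + 1), it was 25.5% (1904 higher, 5556 lower). The first principal component held 65.8% of the variance. The ranges of the groups did not overlap for 58.5% of genes, against 10% for 6 exchangeable libraries, a value that leaves out the pairing by mouse.

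The largest rises picked by the rule included genes almost silent in non-wounded epidermis. Fibroblast, skeletal muscle and red blood cell genes also rose in the wounded libraries, so the cells that hold these transcripts are not known from these values. Mmp10, encoding the matrix metalloproteinase stromelysin-2, rose from 0.0685 ± 0.119 to 19.8 ± 6.18 CPM (log2 8.13, SE 0.56), and the collagenase gene Mmp13 from 0.105 ± 0.0966 to 9.88 ± 3.02 CPM (log2 6.49, SE 0.52). These baselines rest on few counts. Without the non-wounded library of mouse 2 the log2 fold change of Mmp13 was 7.24, and without that of mouse 1 it was 5.91. For Mmp10, all non-wounded counts lay in mouse 3, and without that library its fitted value was 11.84, against 0 counts. Another 5 of these genes had 1 or 2 counts in the whole non-wounded group, so the ratio is given with its 95% exact counting interval. It was 398 (70.9 to 15760) for Mfrp, 201 (35.5 to 7973) for the placental growth factor gene Pgf and 144.5 (39.55 to 1200) for the interferon kappa gene Ifnk. For the late cornified envelope gene Lce3d it was 117 (31.9 to 970.1) and for Zdbf2 115 (31.4 to 955). All non-wounded counts of Mfrp and Zdbf2 lay in mouse 1 and that of Pgf in mouse 2. Without those libraries the fitted log2 values, against 0 counts, went from 8.16 to 9.90 for Mfrp, from 6.57 to 9.08 for Zdbf2 and from 7.17 to 8.91 for Pgf. Mfrp overlaps C1qtnf5 on the same strand, and both together rose by log2 6.74 (SE 0.47). Mfrp also overlaps Rnf26 on the other strand, and Ifnk overlaps Mob3b on the other strand, and strand use is not stated.

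The largest falls picked by the rule included regulators and a late differentiation gene. Tbx3, a T-box transcription factor gene, had 673 counts in the non-wounded libraries (8.73 ± 0.512 CPM) and 0 in all 3 wounded ones, at least 61.2-fold lower against a floor of 3 counts per library. It overlaps the antisense gene Tbx3os1. Tnfsf18, which encodes the ligand of the receptor GITR, fell from 66.0 ± 48.9 to 2.75 ± 0.756 CPM (log2 -4.58, SE 0.52, and log2 -3.82 without the non-wounded library of mouse 3). Tgm3, which encodes a transglutaminase of the cornified envelope, fell from 83.4 ± 22.0 to 8.78 ± 5.04 CPM (log2 -3.24, SE 0.34). The smooth muscle actin gene Acta2 changed by log2 -3.27 (SE 0.45), and by -2.66 without the non-wounded library of mouse 3. Cbfa2t3 changed by -3.87 (SE 0.68), and by -5.26 without the wounded library of mouse 2, and Zfp763 by -3.26 (SE 0.48), and by -3.97 without the wounded library of mouse 3. Cbfa2t3, with a mean of 28.2 counts, overlaps Gm15899 on the same strand (mean 617 counts) and Gm20388 on the other (mean 1193 counts), so its value is uncertain. Hist1h2br (-3.37, SE 0.98) and Sprr2a1 (-3.24, SE 0.95) are uncertain, since they can share reads with near-identical copies. Summed with their copies, the H2b histone genes changed by log2 -0.89 (SE 0.12) and the Sprr2a genes by -1.21 (SE 0.28). For Hist1h2br and Sprr2a1 alone the call ended without the non-wounded library of mouse 2 (adjusted p = 0.0559 and 0.0652 by edgeR) and under DESeq2 (adjusted p = 0.182 and 0.230), with adjusted p from 7.13e-07 to 0.182 and from 9.25e-08 to 0.230 over all alternatives. The log2 values of Hist1h2br and Sprr2a1 were -2.77 and -2.64 without the wounded library of mouse 1, -2.74 and -2.61 without that of mouse 2, and -8.68 and -9.05, against 0 counts, without that of mouse 3.

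**Figure D2:**
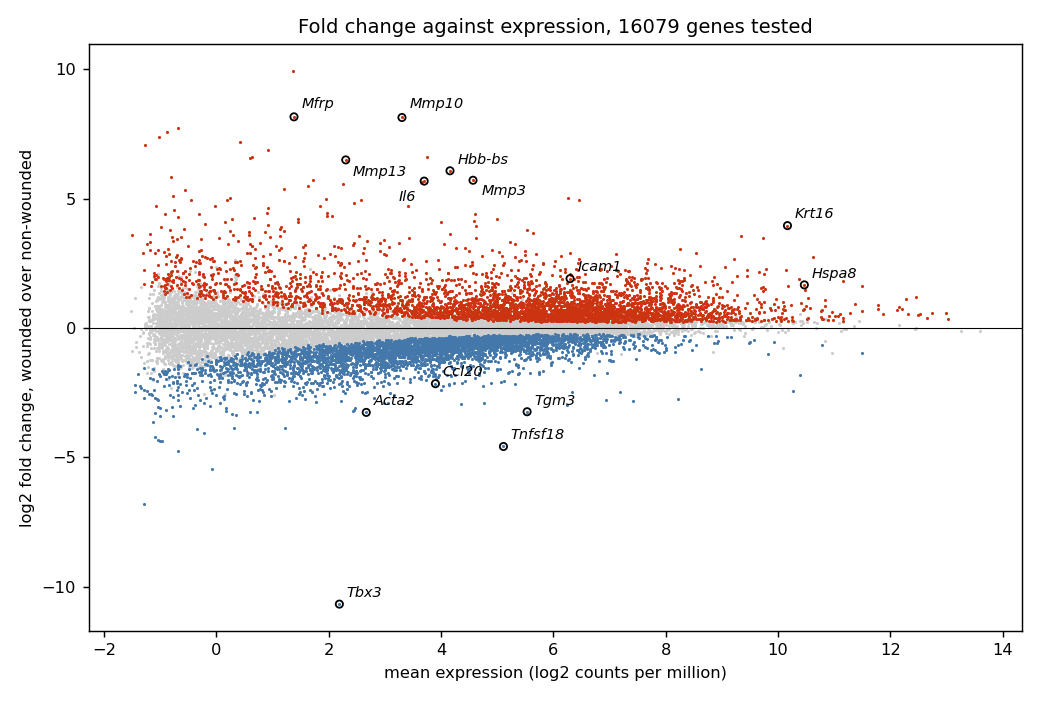
Log2 fold change (wounded over non-wounded) against mean expression (log2 CPM) of the 16079 genes tested, with 3859 higher genes in red and 3917 lower genes in blue at an adjusted p under 0.05 (edgeR), the rest in grey and 14 named genes circled. Hspa8 and Icam1 lie at 1.66 and 1.90, and for Tbx3, plotted at its fitted value against 0 counts, only the bound of at least 61.2-fold lower holds.

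The heat shock and endoplasmic reticulum stress lists were higher in wounded epidermis. Of 22 heat shock genes, 18 rose and none fell, against 14 higher and 4 lower with library totals alone (camera adjusted p = 5.93e-06, and adjusted p = 0.311 with an estimated correlation). Besides Hspa8, the inducible Hsp90 gene Hsp90aa1 rose from 266 ± 19.7 to 901 ± 46.2 CPM (log2 1.76, SE 0.10) and the co-chaperone gene Dnaja1 from 81.1 ± 10.1 to 295 ± 29.1 CPM (log2 1.86, SE 0.12). The near-identical Hsp70 genes Hspa1a and Hspa1b rose together from 368 ± 26.7 to 1819 ± 394 CPM, by log2 2.31 (SE 0.15). Of 15 endoplasmic reticulum stress genes, 9 rose and 2, Herpud1 and Pdia4, fell, against 6 higher and 2 lower with library totals alone (camera adjusted p = 0.0303, and adjusted p = 0.622 with an estimated correlation). The chaperone gene Dnajb9 rose from 36.1 ± 2.14 to 153 ± 1.44 CPM (log2 2.08, SE 0.09), Hyou1 by log2 0.79 (SE 0.10), Calr by 0.66 (SE 0.09) and the BiP gene Hspa5 by 0.80 (SE 0.13). The camera call of this list ended with library totals alone (adjusted p = 0.0611) and without the wounded library of mouse 1 (adjusted p = 0.0874), with camera adjusted p from 0.00931 to 0.622 over all settings. Pdia4 was no longer called without the wounded library of mouse 2 (adjusted p = 0.0545, range 0.000370 to 0.0545).

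Of 21 immediate early genes, 13 rose (14 adjusted over the list alone) and 2, Nr4a1 and Btg2, fell, against 11 higher and 5 lower with library totals alone (camera adjusted p = 0.00356, and adjusted p = 0.342 with an estimated correlation). The mRNA decay factor gene Zfp36 rose by log2 1.25 (SE 0.09), the phosphatase gene Dusp1 by 1.15 (SE 0.09), Ier3 by 1.89 (SE 0.17) and the AP-1 genes Fosl1 and Fos by 1.80 (SE 0.20) and 1.19 (SE 0.21). The nuclear receptor gene Nr4a1 fell from 1213 ± 173 to 596 ± 64.8 CPM and Btg2 from 855 ± 111 to 574 ± 34.7 CPM. Several of these genes were already abundant in non-wounded epidermis, where Fos stood at 302 ± 102 CPM.

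Most NF-kappaB genes rose in the wounded libraries, and cytokine genes changed in both directions. The cells that hold these transcripts were not identified. Of 16 NF-kappaB pathway genes and targets 13 rose and none fell (camera adjusted p = 1.66e-05, and adjusted p = 0.342 with an estimated correlation). The regulator gene Nfkbiz rose from 103 ± 13.9 to 503 ± 40.1 CPM (log2 2.29, SE 0.12), Irf1 by log2 2.29 (SE 0.13), the inhibitor gene Nfkbia by 2.01 (SE 0.14) and Bcl3 by 2.84 (SE 0.22). Of 18 cytokine genes tested, 8 rose and 2, Il18 and Csf3, fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.0446, and adjusted p = 0.586 with an estimated correlation). There were 8 higher and 4 lower with library totals alone, 8 higher and 0 lower with RLE factors and 10 higher and 1 lower with the mouse as a block. Il6 rose from 0.50 ± 0.369 to 25.6 ± 4.34 CPM (log2 5.67, SE 0.40), Il1b from 8.64 ± 2.36 to 59.3 ± 3.22 CPM (log2 2.78, SE 0.17), the IL-1 receptor antagonist gene Il1rn by log2 1.56 (SE 0.09) and the alarmin gene Il33 by 1.52 (SE 0.16). The camera call of the cytokine list ended with the mouse as a block (adjusted p = 0.0567), without the non-wounded or the wounded library of mouse 1 (adjusted p = 0.0698 and 0.0717) and without the wounded library of mouse 3 (adjusted p = 0.0705), with camera adjusted p from 0.00750 to 0.586 over all settings. Both falls were near the threshold. Il18 was not called without the non-wounded libraries of mice 1 and 2 or the wounded ones of mice 1 and 3 in turn (adjusted p = 0.0897, 0.127, 0.0622 and 0.114). Csf3 was not called with the mouse as a block (adjusted p = 0.0771) or without any 1 library other than the non-wounded one of mouse 1 (adjusted p from 0.0525 to 0.324), and its log2 fold change of -1.76 was -0.81 without the non-wounded library of mouse 3.

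Of 13 chemokine genes 6 were higher and 1 lower, against 4 higher and 3 lower with library totals alone and 6 higher and 2 lower with the mouse as a block (camera adjusted p = 0.191, but 0.0367 and 0.0459 without the non-wounded library of mouse 2 or 3, camera range 0.0367 to 0.634). The neutrophil attractant gene Cxcl2 rose from 0.911 ± 0.493 to 10.7 ± 0.202 CPM (log2 3.56, SE 0.32), while Ccl20, encoding the ligand of CCR6, fell from 24.1 ± 4.57 to 5.39 ± 0.888 CPM (log2 -2.16, SE 0.18). In the same libraries the neutrophil receptor genes Csf3r and Cxcr2 were higher, at 1.29 ± 0.319 against 0.223 ± 0.0682 CPM and 4.54 ± 2.10 against 1.71 ± 0.266 CPM. They were the 2 of 13 neutrophil markers with enough counts to test. The 11 others had 119 counts in wounded and 19 in non-wounded libraries, with more in wounded for 9 and in non-wounded for 1. Among them Ly6g had 0 counts in every library.

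Most wound protease genes and wound keratin and antimicrobial genes rose. Of 11 wound protease genes 10 rose and 1, the gelatinase gene Mmp9, fell (camera adjusted p = 0.000224, and adjusted p = 0.342 with an estimated correlation). Besides Mmp10 and Mmp13, Mmp3 rose from 0.898 ± 0.592 to 46.7 ± 11.9 CPM (log2 5.71, SE 0.37) and the urokinase receptor gene Plaur by log2 4.45 (SE 0.38), while Mmp9 went from 24.5 ± 3.97 to 7.76 ± 1.26 CPM. Of 12 wound keratin and antimicrobial genes 11 rose and none fell (camera adjusted p = 9.77e-05, and adjusted p = 0.342 with an estimated correlation). Krt16, a keratin of activated keratinocytes, rose from 139 ± 66.2 to 2162 ± 178 CPM (log2 3.95, SE 0.33), Krt6a from 327 ± 35.8 to 1400 ± 68.4 CPM (log2 2.10, SE 0.11) and the protease inhibitor gene Slpi by log2 4.11 (SE 0.29). Krt6a and its close paralog Krt6b together rose by log2 2.09 (SE 0.11). Fibroblast markers were also higher in these libraries, with Dcn at 11.7 ± 6.93 against 1.14 ± 0.549 CPM. Of 11 growth factor genes 6 rose and none fell, against 5 higher and 3 lower with library totals alone, with Tgfa up by log2 1.77 (SE 0.14), Vegfa by 1.94 (SE 0.26) and Hbegf by 1.12 (SE 0.14). The growth factor list did not pass (camera adjusted p = 0.0584), but it did with library totals alone (adjusted p = 0.0349) and without the non-wounded library of mouse 2 or 3 or the wounded library of mouse 3 (adjusted p = 0.0359, 0.0467 and 0.0326, camera range 0.0326 to 0.342).

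Keratinocyte identity genes moved in both directions. Of 14 basal keratinocyte genes 7 rose and 3 fell, against 5 higher and 5 lower with library totals alone (camera adjusted p = 0.191). The laminin-binding integrin genes Itga3 and Itga6 rose by log2 1.18 (SE 0.09) and 1.52 (SE 0.14), and the hemidesmosome gene Dst and Krt15 changed by -1.83 (SE 0.20) and -0.98 (SE 0.13). Krt14 was 1.45-fold higher, while Krt5 stood at 5418 ± 416 in wounded and 5626 ± 967 CPM in non-wounded libraries (adjusted p = 0.761 by edgeR, but 0.0319 at log2 -0.38 with library totals alone, range 0.0319 to 0.935). Of 18 differentiated keratinocyte genes 5 rose and 1, Tgm3, fell, against 4 higher and 6 lower with library totals alone and 6 higher and 3 lower with the mouse as a block (camera adjusted p = 0.214), with Tgm1 up by log2 1.07 (SE 0.11). Krt1 and Casp14 did not pass, at log2 -0.50 (SE 0.21) and -0.48 (SE 0.20), but were called as lower with the mouse as a block (adjusted p = 0.000315 and 0.0201, ranges 0.000164 to 0.294 and 0.000421 to 0.303) and with library totals alone. Krt1 was also called without the wounded library of mouse 1 or the non-wounded one of mouse 2 (adjusted p = 0.0112 and 0.0412) and Casp14 without the non-wounded one of mouse 3 (adjusted p = 0.0174). Krt10, the most abundant transcript in each of the 6 libraries, did not pass (log2 -0.12, SE 0.13), but was called as lower with library totals alone (log2 -0.44, adjusted p = 0.0139, range 0.0139 to 0.945). Of 11 hair follicle and sebaceous genes 4 rose and 1, Lhx2, fell, against 2 higher and 2 lower with library totals alone (camera adjusted p = 0.432). Sox9, a transcription factor gene of the follicle, rose from 71.5 ± 10.3 to 274 ± 11.9 CPM (log2 1.94, SE 0.11).

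Genes of the gd T cells and of ligands for them changed in both directions. For comparison, 48.4% of all genes tested were called. Of 17 dendritic epidermal T cell genes 2, Sema4d and Il2rb, rose and 6 fell (camera adjusted p = 0.191). There were 2 higher and 12 lower with library totals alone and 2 higher and 8 lower with the mouse as a block. Sema4d, a ligand of plexin B2, rose by log2 1.39 (SE 0.17) and the IL-2 and IL-15 receptor chain gene Il2rb by 1.07 (SE 0.15). The CD3 chain gene Cd3g changed by -0.85 (SE 0.22), Cd7 by -0.66 (SE 0.16) and Thy1 by -0.35 (SE 0.10). Trdc, the constant region of the delta chain, stood at 33.8 ± 1.84 in wounded and 37.3 ± 6.06 CPM in non-wounded libraries (adjusted p = 0.397 by edgeR, but 0.0114 at log2 -0.47 with library totals alone, range 0.0114 to 0.945). Of 7 T cell activation genes 1, the 4-1BB gene Tnfrsf9, rose (log2 1.30, SE 0.32), against 1 higher and 2 lower with library totals alone and 1 higher and 1 lower with the mouse as a block (camera adjusted p = 0.716). The other 6 genes of that list, among them Ifng and Il17a, had too few counts, so a change in them was not detectable at this depth.

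Among 12 genes for ligands and costimulators of these cells 4 rose and 5 fell, against 4 higher and 6 lower with library totals alone (camera adjusted p = 0.830, with a mean log2 fold change of 0.01, a median of -0.54 and camera's direction lower). The costimulator gene Cd86 rose from 8.73 ± 2.12 to 38.5 ± 1.81 CPM (log2 2.14, SE 0.17), the 4-1BB ligand gene Tnfsf9 by log2 3.82 (SE 0.49), the junctional receptor gene Cxadr by 1.21 (SE 0.13) and the plexin B2 gene Plxnb2 by 0.67 (SE 0.08). The cytokine gene Il15 fell from 11.3 ± 3.68 to 2.34 ± 0.684 CPM, and the NKG2D ligand gene H60c, Cd48 and Skint3 changed by log2 -0.96 (SE 0.15), -1.75 (SE 0.29) and -0.65 (SE 0.17). Skint1 did not pass (log2 0.23, SE 0.15, and log2 -0.09 with library totals alone). In the leukocyte adhesion list, which holds Icam1, 5 of 12 rose (6 adjusted over the list alone) and 3 fell, against 4 higher and 4 lower with library totals alone (camera adjusted p = 0.451). Cd44 and Itga5 rose by log2 2.28 (SE 0.18) and 1.75 (SE 0.25), and Cd47, Itgae and the LFA-1 beta chain gene Itgb2 changed by -0.76 (SE 0.09), -0.73 (SE 0.16) and -1.02 (SE 0.17).

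The Langerhans cell, monocyte and macrophage, melanocyte and Merkel cell, and interferon response lists did not pass camera as groups. Of 13 Langerhans cell genes 4 rose and 2 fell, against 2 higher and 6 lower with library totals alone and 5 higher and 4 lower with the mouse as a block (camera adjusted p = 0.705). The langerin gene Cd207 rose from 73.0 ± 14.1 to 260 ± 26.3 CPM (log2 1.83, SE 0.14), while Csf1r changed by log2 -1.20 (SE 0.15). Of 8 monocyte and macrophage genes 3, Cd14, Lyz2 and Cd68, rose and 1, Adgre1, fell, against 2 higher and 2 lower with library totals alone (camera adjusted p = 0.359), with Cd14 up by 2.89 (SE 0.48). Cd68 was not called without the non-wounded or the wounded library of mouse 2 (adjusted p = 0.0586 and 0.0736, range 0.00500 to 0.365). Of 9 melanocyte and Merkel cell genes 2, Krt8 (log2 3.34, SE 0.77) and Pmel, rose (camera adjusted p = 0.109). Without the non-wounded library of mouse 2 this list passed (adjusted p = 0.0341, camera range 0.0341 to 0.586) and Pmel did not (adjusted p = 0.0586, range 0.0154 to 0.189). Of 12 interferon response genes 2, Irf7 (log2 1.47, SE 0.18) and Rsad2, rose and 3, among them Usp18 and Bst2, fell, against 1 higher and 6 lower with library totals alone (camera adjusted p = 0.389). Rsad2 was not called without any 1 library other than the non-wounded one of mouse 3 (adjusted p from 0.0543 to 0.123), nor Bst2 without any 1 other than the wounded one of mouse 3 (adjusted p from 0.0667 to 0.103).

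The fibroblast, skeletal muscle and red blood cell lists were higher in wounded libraries. Of 11 fibroblast markers 8 rose and 1, Col6a1, fell (camera adjusted p = 0.0101, and adjusted p = 0.411 with an estimated correlation). The collagen gene Col1a2 rose from 1.45 ± 1.06 to 10.7 ± 2.01 CPM (log2 2.90, SE 0.41, and log2 3.67 without the non-wounded library of mouse 3), the proteoglycan gene Dcn by log2 3.35 (SE 0.47) and Dpt by 4.21 (SE 0.63), or 5.11 without the non-wounded library of mouse 1. Col6a1 was not called without the non-wounded libraries of mice 1 and 3 or the wounded ones of mice 1 and 2 in turn (adjusted p from 0.0626 to 0.0759). Sparc did not pass, at 33.1 ± 5.71 in wounded and 36.1 ± 11.9 CPM in non-wounded libraries. Of 7 skeletal muscle genes 5 rose and none fell (camera adjusted p = 0.00520, and adjusted p = 0.311 with an estimated correlation). They remained low, with Acta1 at 4.25 ± 1.46 CPM in wounded libraries (log2 3.74, SE 0.51, and log2 4.59 without the non-wounded library of mouse 3), Myh4 at 1.16 ± 0.0533 CPM (log2 3.81, SE 0.60, and log2 4.69 without the non-wounded library of mouse 1) and Atp2a1 at 2.49 ± 0.183 CPM (log2 1.96, SE 0.33). All 5 red blood cell genes rose (camera adjusted p = 0.00356, and adjusted p = 0.342 with an estimated correlation). The similar beta-globin genes Hbb-bs and Hbb-bt together rose from 0.620 ± 0.226 to 39.8 ± 12.1 CPM, by log2 5.98 (SE 0.29), and the alpha-globin genes Hba-a1 and Hba-a2 from 22.4 ± 3.83 to 81.7 ± 23.4 CPM, by log2 1.87 (SE 0.20). Hbb-bt alone rose by 5.36 (SE 0.55), or 6.10 without the non-wounded library of mouse 2. Of 4 adipocyte genes tested, too few for a test of the list, 2, Car3 and Fabp4, rose (3 adjusted over the list alone), with Car3 at 3.55 ± 0.399 against 0.306 ± 0.198 CPM. Fabp4 rose by log2 4.65 (SE 0.79), or 6.35 without the non-wounded library of mouse 1 and 4.01 without the wounded library of mouse 3. The adipocyte list reached 5 tested members, and passed camera, without the wounded library of mouse 1 (adjusted p = 0.0231) or any 1 of the non-wounded libraries of mice 1, 2 and 3 (adjusted p = 0.0358, 0.0338 and 0.00725). Of 3 endothelial genes with enough counts 1, Vwf, was lower (0 adjusted over the list alone), at 1.89 ± 0.422 against 3.25 ± 0.526 CPM (adjusted p = 0.0451 by edgeR). The 8 endothelial markers with too few counts to test each had more counts in wounded libraries, 102 against 55 in sum. Vwf was not called without any 1 library other than the wounded one of mouse 1 (adjusted p from 0.0566 to 0.138).

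**Figure D3:**
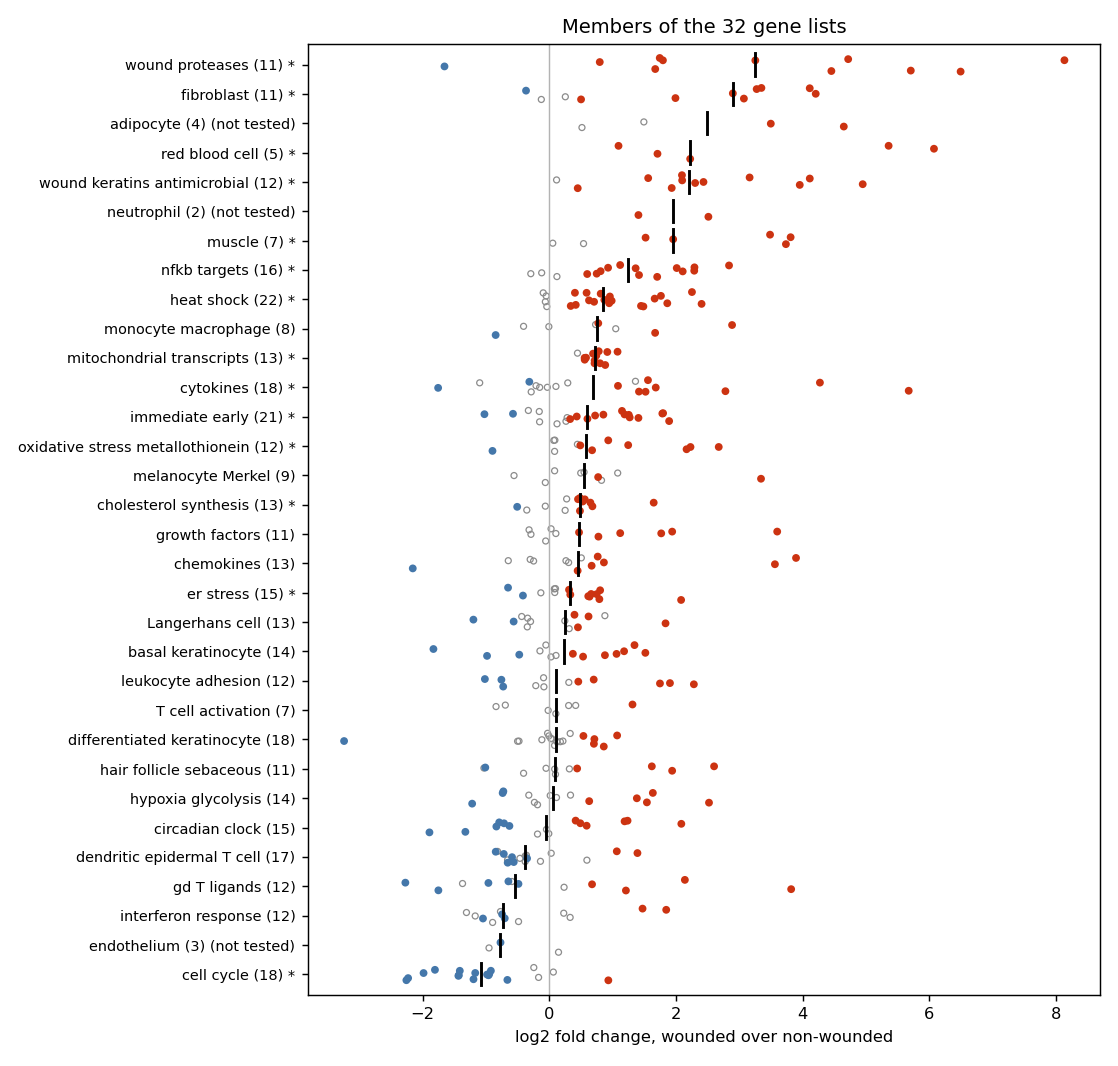
Log2 fold change (wounded over non-wounded) of each tested member of the 32 gene lists, filled in red (higher) or blue (lower) where the adjusted p was under 0.05 (edgeR) and open otherwise, with a black bar for the median, the number of tested members in brackets and an asterisk for lists past the camera threshold. Of the 14 lists with an asterisk 13 have their median above 0 and 1, the cell cycle list, has it below 0 under TMM scaling and with library totals alone.

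Most cell cycle genes fell. Of 18 cell cycle genes 14 fell and 1, Pcna, rose, against 1 higher and 16 lower with library totals alone (camera adjusted p = 0.00515, and adjusted p = 0.634 with an estimated correlation, and adjusted p = 0.0757 with fry). The mitotic kinase gene Aurkb fell from 8.19 ± 1.86 to 1.75 ± 0.802 CPM (log2 -2.23, SE 0.33), the cyclin B1 gene Ccnb1 from 21.2 ± 4.88 to 6.02 ± 2.74 CPM (log2 -1.81, SE 0.29), and the proliferation marker gene Mki67 changed by log2 -0.98 (SE 0.22). Pcna, which encodes the DNA polymerase clamp that also serves in DNA repair, rose from 88.4 ± 9.34 to 169 ± 5.12 CPM (log2 0.93, SE 0.10).

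The oxidative stress, cholesterol and mitochondrial lists were higher in wounded epidermis. Of 12 oxidative stress and metallothionein genes 7 rose and 1, Nqo1, fell (camera adjusted p = 0.00520, and adjusted p = 0.311 with an estimated correlation). The metal-binding protein gene Mt1 rose from 112 ± 19.6 to 527 ± 66.2 CPM (log2 2.23, SE 0.14), the sulfiredoxin gene Srxn1 by log2 2.67 (SE 0.19) and the thioredoxin reductase gene Txnrd1 by 1.25 (SE 0.09). Nqo1 was not called without the non-wounded library of mouse 1 or 2 (adjusted p = 0.0582 and 0.0584, range 0.000348 to 0.0584). Of 13 cholesterol synthesis and uptake genes 8 rose and 1, Lss, fell (2 lower adjusted over the list alone), against 3 higher and 3 lower with library totals alone and 9 higher and 2 lower with the mouse as a block (camera adjusted p = 0.0486, and adjusted p = 0.634 with an estimated correlation). The regulator gene Srebf2 rose by log2 0.65 (SE 0.11) and the squalene epoxidase gene Sqle by 0.68 (SE 0.14). The camera call of the cholesterol list ended with library totals alone (adjusted p = 0.0754), without the wounded libraries of mice 1 and 2 in turn (adjusted p = 0.117 and 0.0501) and without the non-wounded ones of mice 2 and 3 in turn (adjusted p = 0.0598 and 0.0768), with camera adjusted p from 0.0120 to 0.634 over all settings. Of 13 mitochondrially encoded transcripts 12 rose (13 adjusted over the list alone) and none fell, against 9 higher and 0 lower with library totals alone (camera adjusted p = 0.000226, and adjusted p = 0.586 with an estimated correlation), with mt-Nd2 up by log2 1.08 (SE 0.12), mt-Nd1 by 0.92 (SE 0.12) and mt-Cytb by 0.88 (SE 0.14). All symbols starting with mt-, these 13 among them, took 4.59%, 4.55% and 4.18% of counts in the wounded libraries of mice 1, 2 and 3. Their share was 3.15%, 4.10% and 2.90% in the non-wounded ones. Of 14 hypoxia and glycolysis genes 5 rose (6 adjusted over the list alone) and 3, Bnip3, Pdk1 and Egln3, fell, against 5 higher and 5 lower with library totals alone (camera adjusted p = 0.389). The hexokinase gene Hk2 rose from 25.9 ± 4.87 to 148 ± 22.9 CPM (log2 2.52, SE 0.16). Egln3 was not called without the non-wounded library of mouse 2 (adjusted p = 0.0613, range 3.36e-07 to 0.0613). Of 15 circadian clock genes 6 rose and 6 fell, against 3 higher and 8 lower with library totals alone (camera adjusted p = 0.857), with Cry1 up by log2 2.08 (SE 0.15), Arntl by 1.19 (SE 0.13), and Per1 and Per3 changed by -0.84 (SE 0.09) and -1.33 (SE 0.16). Whether the groups were collected at the same time of day is not known here.

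In all, 13 of the 29 lists tested passed as higher and 1 as lower. None of these 14 calls held with an estimated correlation, and 13 were also called by fry. Fry called 18 lists as higher and 0 as lower, and it tests a list's genes against no change and not against other genes. It added the leukocyte adhesion, growth factor and basal keratinocyte lists (fry adjusted p = 0.0314, 0.00346 and 0.0282). It also added the hair follicle and sebaceous and the melanocyte and Merkel cell lists (fry adjusted p = 0.0282 and 0.0295). With library totals alone the single-gene calls of Krt14, Postn, mt-Co1, Pmel, Rsad2 and Cd68 ended.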

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

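Scaling by library totals alone was chosen after seeing the data, and the other settings before. Under library totals 2168 genes were higher and 6655 lower, and with log2(TPM + 1) and log2(TPM + 0.1) 1904 and 1895 were higher, against 3859 higher and 3917 lower. None of these 3 uses the TMM factors. Asking for a change of at least 2-fold left 1414 higher and 1567 lower genes. Leaving out a library gave 3153 to 3597 higher and 3147 to 3600 lower genes. Of the lists, 0 were higher and 0 lower with an estimated correlation, and 18 were higher and 0 lower with fry, against 13 and 1. Leaving out a library gave 11 to 16 higher lists. List members summed over the lists that were lower numbered 60, against 108 with library totals, 94 with log2(TPM + 1) and 98 with log2(TPM + 0.1). Hspa8 and Icam1 were called as higher under each setting, at log2 1.61 to 1.70 and 1.82 to 1.98 without a library.

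For 167 other genes picked by the rule or as examples the settings gave 2668 values, of which 2561 kept direction and side of the threshold, 81 kept the direction and lost the call, and 3 changed direction, while the rest gained a call. Those gains were Krt5, Krt10 and Trdc with library totals and log2(TPM + 0.1), Krt10 with log2(TPM + 1), and Krt1 and Casp14 under several settings, the block among them. The changes of direction were in the Skint1 log2 fold change with library totals (-0.092) and, without the non-wounded library of mouse 1, in those of Krt5 and Sparc, none of them called. Leaving out a library gave log2 -0.14 to 0.090 for Krt5 and -0.29 to 0.17 for Sparc. The cause of these changes was not tested. With log2(TPM + 1) the calls of 14 of these genes ended, among them Srebf2, Sqle, Hspa5, Plxnb2, Krt14, Cxcr2 and Csf3r. With the mouse as a block (4212 genes higher, 4351 lower) the cytokine list and Csf3 were no longer called, and among the lists and these genes it ended no other call, and it moved the number of lower members of 6 lists by over 1.5 times. Depth limits the lists of neutrophil, endothelial and adipocyte markers, most of which had too few counts to test.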

Other observations

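The gene families of this part were picked by their names after the data were seen, so the camera tests of these families were chosen after the result was seen, while the tests of splits and of explanations were set out before their results, except for a minimum of 5 endothelial markers and the share of genes moved by a correction. Genes for making ribosomes rose in wounded epidermis. Of 49 ribosome biogenesis genes 41 rose and none fell, with a median log2 fold change of 0.84, against 0.51 and 30 higher and 3 lower with library totals alone (camera adjusted p = 2.68e-11, and adjusted p = 0.359 with an estimated correlation). Tsr1 rose by log2 1.98 (SE 0.10) and the nucleolin gene Ncl from 427 ± 14.5 to 1243 ± 153 CPM (log2 1.54, SE 0.11). Of 80 cytosolic ribosomal protein genes 55 rose and none fell, with a median of 0.30, against -0.02 and 2 higher and 2 lower with library totals alone (camera adjusted p = 5.47e-08, and adjusted p = 0.470 with an estimated correlation). Of 38 proteasome subunit genes 19 rose and 3 fell, with a median of 0.23, against -0.09 and 3 higher and 12 lower with library totals alone (camera adjusted p = 0.00651, and adjusted p = 0.470 with an estimated correlation). Of 37 nuclear NADH dehydrogenase subunit genes 3 fell, against 0 higher and 26 lower with library totals alone (camera adjusted p = 0.189), and of 17 tRNA synthetase genes 7 rose and 4 fell, against 5 higher and 8 lower with library totals alone (camera adjusted p = 0.299).

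Tubulin and small proline rich genes were higher as lists and replication histone genes lower. Of 12 tubulin genes 8 rose and 2 fell, with a median of 0.93, against 0.61 and 7 higher and 3 lower with library totals alone (camera adjusted p = 0.00296, and adjusted p = 0.347 with an estimated correlation). Tubb6 rose from 2.21 ± 0.0353 to 46.6 ± 11.4 CPM (log2 4.39, SE 0.20) and Tuba4a by log2 1.81 (SE 0.10). Of 13 small proline rich genes, near-identical in part, 9 rose and 3 fell, with a median of 2.75, against 2.42 and 9 higher and 3 lower with library totals alone (camera adjusted p = 0.00296, and adjusted p = 0.470 with an estimated correlation). Sprr1a rose from 408 ± 104 to 2745 ± 365 CPM and Sprr2g by log2 3.10 (SE 0.17). Of 13 replication histone genes 8 fell and none rose, with a median of -1.02, against -1.34 and 0 higher and 11 lower with library totals alone (camera adjusted p = 0.00604, and adjusted p = 0.347 with an estimated correlation), with Hist1h2bc changed by -0.70 (SE 0.12). Libraries made by poly-dT capture count only transcripts with a poly(A) tail. Histone transcripts without one were not measured, so these values do not give the whole histone output.

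Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 7776 called genes and the highest other gave 0, and 2 gave as many as 14 called lists. The other split with 14 lists set both libraries of mouse 3 and the non-wounded library of mouse 1 against the rest, so it parted the pair of only 1 mouse. Among the splits that part all 3 pairs the highest other gave 11 lists. With 10 splits a share under 0.05 cannot be reached. Each other split also mixes wounded and non-wounded libraries, so the difference between them adds to the spread within its groups. The groups of each other split also hold unequal numbers of wounded libraries, so part of the difference remains between them. Neither its count of 0 called genes nor its count of called lists is therefore the number to be had without a difference.

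Collagen and haemoglobin transcripts were higher in wounded libraries of an epidermis that was separated from dermis, and RNA carried over from other tissue of the wound may be a source. The values argue against scaling as the source of the fibroblast rise. Among 4 scalings, library totals alone moved log2 fold changes the most, by -0.32 (median over genes). The fibroblast median was 2.90 under TMM, so shifts of this size could hardly bring it to the bound of 0.5 set beforehand. Its lowest median over the 4 scalings was 2.57 (SE of the median 0.99, by bootstrap over genes), above that bound. The red blood cell list was not in this test and had a median of 1.90 with library totals alone. Carried-over fibroblasts stay open, since 72.7% (binomial SE 13.4 over markers) of the fibroblast markers rose, between the 50% and 75% set beforehand as bounds. Postn and Sparc also stood at 363 ± 30.1 and 36.1 ± 11.9 CPM in non-wounded epidermis already. The SEs of these tests over markers treat genes as independent. Dermal tissue with its vessels had a median of -0.78 (bootstrap SE 0.43) over the 3 endothelial markers tested, below the bound of 0 set beforehand as counting against it, while the 8 with too few counts all had more in wounded libraries (102 against 55 in sum). It is left open because 3 of 11 is under the minimum of 5 used for lists, a reason applied after the value was seen. The other markers also went the opposite way, so these 2 tests cannot tell either carry-over apart from a response of the epidermis itself. Values outside these tests went with RNA from other tissue or blood, though no bound was set for them. Of 7 skeletal muscle genes 5 rose and none fell, and the 6 untested ones had 150 counts in wounded and 54 in non-wounded libraries. Of 4 adipocyte genes 2 rose and none fell, and the beta-globin genes rose by log2 5.98 (SE 0.29). The smooth muscle actin gene Acta2 went the other way (log2 -3.27).

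The alpha to beta globin ratio was 46.8, 27.9 and 39.8 in the non-wounded libraries of mice 1, 2 and 3, and 2.01, 2.19 and 1.98 in the wounded ones.

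Zinc finger genes were lower in wounded libraries as a family, since of 346 genes named Zfp, Zkscan or Zscan, 152 fell, 43.9% against 24.4% of all genes, and 49 rose, with a median of -0.43, against -0.75 and 30 higher and 208 lower with library totals alone (camera adjusted p = 9.61e-05, and adjusted p = 0.359 with an estimated correlation). Zfp282 and Zkscan8 changed by log2 -2.26 (SE 0.13) and -2.12 (SE 0.12), and Zfp131 rose by 1.45 (SE 0.10). Transcript length and GC content are unlikely as the whole cause, since a smooth correction for both left the median at -0.43, against -0.43 before it. The SE was 0.0583, by bootstrap over genes, and the correction moved 29.4% of the other genes by over 0.1. Low expression could account for part. The family's median lay -0.26 (SE 0.0545, also over genes) from that of genes matched on expression, between the bounds of -0.1 and -0.3 set beforehand. An effect of low expression therefore cannot be told apart here. Both SEs treat genes as independent, which they are not, so they may be too small. A shorter life or lower synthesis of these transcripts after wounding was not tested.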
